A study of Mus musculus with 4 samples.

How the data were processed

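Gene expression was measured by RNA-seq in mouse cells sorted by fluorescence as otic cells. They came from otocysts, the closed epithelial vesicles from which the inner ear forms. The labels name 4 libraries, 2 from control embryos and 2 labelled Brg1cKO, for a conditional knockout of Brg1. Each library was made from 3000 cells, with random-primed, strand-specific SMART-seq chemistry, and was read from a single end over 75 bp, per the labels' protocols. The labels do not say whether the replicates came from separate litters, embryos or sorts, so the p-values measure only the spread between these libraries, which may be technical.

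The authors deposited raw read counts per gene, as whole numbers under Ensembl gene identifiers, with no normalization. HISAT2, HTSeq and DESeq2 and the mm10 build are named in the submitters' processing notes, with no role or version. The strand setting and the gene annotation used for the counting are not given in the sources used here, so reads of overlapping genes on opposite strands may have been assigned to either. The last 5 lines of each table name no gene and were kept out of library sizes and tests. They held the records outside any gene, which were 21.0%, 21.6%, 14.5% and 15.0% of all records in control replicates 1 and 2 and Brg1cKO replicates 1 and 2. They also held the records that were ambiguous (2.23%, 2.20%, 3.00% and 2.95%), not aligned (20.9%, 19.1%, 9.54% and 9.41%) or not uniquely aligned (7.63%, 7.76%, 8.95% and 9.01%), and 0 records of low alignment quality.

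Gene symbols and positions were taken from GENCODE release M21 of the same build, which matched 52403 of 52636 identifiers. The counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10, which left 16557, and libraries were scaled by TMM. A quasi-likelihood model with robust moderation in its installed default form was fitted to the 4 libraries with group as its term, and the quasi-likelihood F-test was applied to the group. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are of Brg1cKO over control, and values per library are TMM-scaled CPM, the reads of a gene relative to the scaled total of its library. The test, the alternatives, the rule for named genes and 43 gene lists were fixed before the data were examined. The lists came from textbook knowledge of otic development, signalling, stress and the other cell types a sort from this region could hold, and some genes stand in several lists. Each list was tested against all other genes with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and adjustment over the 43 lists. Camera with an estimated correlation and fry were run beside it. With 4 libraries and 2 groups, the estimated correlation rests on 2 residual degrees of freedom.

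The rule for named genes took Smarca4 and Sox2, up to 12 called genes in each direction with an average log2 CPM of at least 3, up to 4 members of each list with the smallest p whether or not they passed, up to 3 members with the highest CPM of lists for other cell types, stress or RNA quality, and the 5 genes with the highest counts. Genes outside this rule are named as such, or are members of gene lists added later, picked by no fixed rule. For a gene at 0 in both libraries of a group, a fold is given as a lower bound against 3 counts over the group. Such bounds cover counting error only, since reads without molecular identifiers are not independent molecules.

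The fits were tested on simulated counts with the means and library sizes of these libraries and dispersions estimated by edgeR. Each setting was drawn a single time. Changed genes came only from those above a minimum average CPM, so recovery at lower counts was not measured. With 200 of 15745 genes changed and a separate spread for each group, edgeR recovered 0% of genes changed by 2-fold, 26% by 4-fold, 62% by 8-fold and 78% by 16-fold, with 3 false calls among 86. With no gene changed it made 0 calls, while DESeq2 1.42.0 made 101. Camera recovered a simulated list of 30 genes shifted by 4-fold and called 1 of 20 random lists. With an estimated correlation the shifted list had an adjusted p of 0.0408 and 0 random lists were called. Simulated genes were drawn independently of each other, so this could not test false calls on lists of co-expressed genes. Other settings fixed in advance numbered 17 and covered other scalings, low-count filters, tools, moderation and thresholds, a set of genes without mitochondrial, ribosomal protein and haemoglobin genes, the replicate number as a block, and each library left out. Chosen after seeing the data were 3 more, namely the newer edgeR moderation, libraries thinned to the same depth, and limma voom with sample quality weights. The newer moderation had been fitted ahead of the installed default and gave 70 calls. The default was kept as the main test because the design fixed in advance named the function without that option.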

Results

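RNA from cells sorted as otic was compared between 2 control libraries and 2 libraries labelled Brg1cKO. Both groups also held transcripts of other cell types. Cdh5, an endothelial gene, averaged 705 CPM in the controls and 780 CPM in the others. The control libraries held 15357265 and 19132360 reads in genes, and the libraries labelled Brg1cKO held 29361382 and 25875555. At least 1 read was found for 17266 and 17086 genes in the controls and for 20859 and 20902 genes in the libraries labelled Brg1cKO. The share of records that fell in genes was 48.2% and 49.3% in the controls and 64.0% and 63.7% in the others, so the groups differed in library composition as well as in label. The spread between replicates exceeded read-counting error, with a chi-square per degree of freedom of 119 between the controls and 44.0 between the libraries labelled Brg1cKO. That measure treats amplified reads as independent molecules, so it covers counting error only. The log2 ratio between replicates had an SD of 2.30 over all tested genes in the controls and 1.27 in the other group. Mitochondrial transcripts made up 2.63% and 2.68% of gene reads in the controls and 2.44% and 2.43% in the others.

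The series title asks how the chromatin remodeler Brg1 acts on the activation of Sox2 and on the identity of the cells that give rise to neurons and sensory cells. Smarca4, the gene for Brg1, stood at 815 ± 0.888 CPM (SD, n = 2) in the controls and at 870 ± 30.5 CPM (SD, n = 2) in the libraries labelled Brg1cKO. Its log2 fold change was 0.09 ± 0.0995 (SE), with a 95% interval from -0.14 to 0.33 and an adjusted p of 0.817 by edgeR. Smarca4 (ENSMUSG00000032187) lies on chromosome 9 from 21616169 to 21704230 in mm10. Its count takes in reads outside any deleted exons, which the labels do not give, so it checks the labels little, and the direction of every difference rests on the labels alone. Sox2, a transcription factor of sensory and neural progenitors (ENSMUSG00000074637, chromosome 3, 34650405 to 34652461, 1 exon), stood at 12.1 and 16.7 CPM in the controls and at 30.1 and 33.6 CPM in the libraries labelled Brg1cKO. Its log2 fold change of 1.14 ± 0.577 (SE), with a 95% interval from -0.21 to 2.50, did not pass (adjusted p = 0.511, edgeR).

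Oc90, which encodes the main matrix protein of otoconia and marks otic epithelium, fell from 757 ± 35.0 CPM in the controls to 46.9 ± 3.18 CPM (SD, n = 2 each) in the libraries labelled Brg1cKO. Col2a1, a cartilage collagen also made by otic epithelium, fell from 1718 ± 8.97 to 792 ± 30.7 CPM. Nefm, a neurofilament subunit of neurons, fell from 654 ± 88.2 to 205 ± 7.94 CPM. Mrc1, the macrophage mannose receptor, rose from 59.0 ± 17.9 to 410 ± 19.2 CPM, and Tmsb4x, an actin-binding peptide abundant in blood cells, rose from 856 ± 2.10 to 1612 ± 20.6 CPM. These 5 genes were all that passed among 16557 tested by edgeR, 2 higher and 3 lower. Their log2 fold changes were -4.01 ± 0.155 for Oc90 (adjusted p = 0.000326), -1.12 ± 0.0882 for Col2a1 (0.0270) and -1.67 ± 0.151 for Nefm (0.0371). For Mrc1 and Tmsb4x they were 2.80 ± 0.249 and 0.91 ± 0.0861 (0.0371 each). In mm10, Oc90 lies on chromosome 15 (65876053 to 65912397), Col2a1 on chromosome 15 (97975602 to 98004695), Nefm on chromosome 14 (68082590 to 68124846), Mrc1 on chromosome 2 (14229392 to 14332057) and Tmsb4x on the X chromosome (167207093 to 167209315). Nefm shares 1108 exonic bases with Nefl on the opposite strand, so its count is uncertain if the counting ignored strand.

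**Figure D1:**
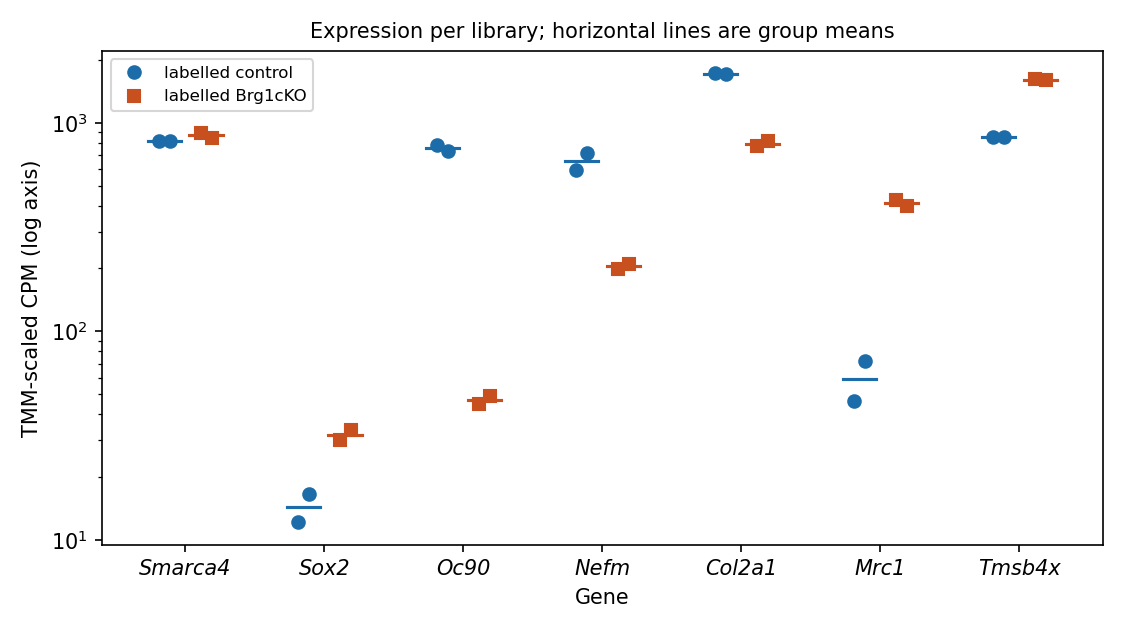
TMM-scaled CPM (log axis) of Smarca4, Sox2 and the 5 genes that passed the test, with 1 point per library (circles, control; squares, labelled Brg1cKO) and a line at each group mean. Oc90 stands at 782 and 732 CPM in the controls and at 44.6 and 49.1 CPM in the libraries labelled Brg1cKO.

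At an unadjusted p under 0.05, 2063 genes differed, 1269 higher and 794 lower, where 828 would be expected by chance. That excess depended on the libraries too, with 508 of 19010 genes without Brg1cKO replicate 1 and 534 of 19073 without Brg1cKO replicate 2, both fewer than chance gives, and 5718 and 5604 without control replicates 1 and 2. With a lone library in a group, the fit takes its spread from the other group. The SD of the log2 ratio between replicates was 2.30 in the controls and 1.27 in the others. The count of 5 depended strongly on which group supplied the spread, and on the tool. It became 3519 without control replicate 1 and 3355 without control replicate 2, 45 without Brg1cKO replicate 1 and 33 without Brg1cKO replicate 2, and 2422 with DESeq2, which also made 101 calls on simulated counts with no change.

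Genes of the otic placode and vesicle fell as a set in the libraries labelled Brg1cKO. Of 27 measured members, 24 had negative log2 fold changes, with a median of -1.02 (camera adjusted p = 8.46e-20, limma; adjusted p = 0.176 with an estimated correlation). Oc90 and Col2a1 passed over all genes tested, and 16 members were lower and 1 higher when adjusted over the list alone. Epcam, an epithelial adhesion molecule, stood at 144 and 205 CPM in the controls and 42.8 and 37.1 CPM in the others. In the same libraries the white blood cell list had a median of 2.11 and the myogenic list 2.81.

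Regional otic lists fell too, in libraries where the white blood cell and myogenic lists had medians of 2.11 and 2.81. For lateral and nonsensory genes, 9 of 10 measured members were negative, with a median of -1.98 (camera adjusted p = 1.68e-16; adjusted p = 0.176 with an estimated correlation), and 7 were lower when adjusted over the list alone. Otx1, a transcription factor of lateral and ventral otic epithelium, stood at 36.4 and 80.1 CPM in the controls and 1.40 and 2.08 CPM in the libraries labelled Brg1cKO. Tbx2 stood at 392 and 215 against 60.7 and 74.6 CPM. For ventral and cochlear genes, 9 of 11 were negative, with a median of -1.96 (camera adjusted p = 5.25e-07; adjusted p = 0.18 with an estimated correlation), and 6 were lower and 1 higher when adjusted over the list alone. Pax2, needed for the cochlea, stood at 81.0 and 120 against 20.4 and 6.94 CPM. For dorsal and vestibular genes, 12 of 17 were negative, with a median of -0.74 (camera adjusted p = 0.00151; adjusted p = 0.267 with an estimated correlation), and the lowest adjusted p over the list alone was 0.0503, for Lmx1a. Gbx2 in this list stood at 20.3 and 40.8 against 3.11 and 4.63 CPM.

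Genes of otic neuroblasts and early neurons fell as a set, with 25 of 29 measured members negative and a median of -1.26 (camera adjusted p = 5.63e-12; adjusted p = 0.18 with an estimated correlation). The white blood cell and myogenic lists had medians of 2.11 and 2.81 in the same libraries. The lowest adjusted p over all genes tested was 0.121, for Ina, and 13 members were lower when adjusted over the list alone. Ina, a neuronal intermediate filament, stood at 83.5 and 110 CPM in the controls and 22.6 and 18.6 CPM in the libraries labelled Brg1cKO, and Elavl3, a neuronal RNA-binding protein, stood at 84.5 and 84.3 against 27.2 and 21.6 CPM. The prosensory list, which holds Sox2, had 11 of 16 members negative and a median of -0.51 (camera adjusted p = 0.00422; adjusted p = 0.297 with an estimated correlation). Within it Eya1 stood at 116 and 210 against 35.4 and 46.7 CPM, and it was lower when adjusted over the list alone. The prosensory call was lost without control replicate 1 (adjusted p = 0.164) and without Brg1cKO replicate 2 (adjusted p = 0.103). The hair cell list had 8 measured members, 4 negative and 4 positive (camera adjusted p = 0.954).

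White blood cell genes rose as a set in the libraries labelled Brg1cKO. All 17 members were positive, with a median log2 fold change of 2.11 (camera adjusted p = 2.93e-23; adjusted p = 0.176 with an estimated correlation). Mrc1 passed over all genes tested, and 12 were higher when adjusted over the list alone. Csf1r, the receptor that macrophages need to survive, stood at 106 and 56.7 CPM in the controls and 298 and 289 CPM in the libraries labelled Brg1cKO. Coro1a, an actin regulator of white blood cells, stood at 51.1 and 45.9 against 214 and 205 CPM. Red blood cell genes moved the other way, with 11 of 13 members negative and a median of -1.49 (camera adjusted p = 0.000704; adjusted p = 0.267 with an estimated correlation). Without mitochondrial, ribosomal protein and haemoglobin genes the call was lost (adjusted p = 0.459), with 7 members left, 5 of them negative, and a median of -0.32 (quartiles -2.22 and 0.34). Among these Slc4a1, the red cell anion exchanger, stood at 36.4 and 25.1 CPM in the controls and 7.58 and 5.05 CPM in the others. Hbb-y, an embryonic globin, stood at 224 and 372 against 95.5 and 81.2 CPM. Endothelial transcripts were abundant in every library, with Cdh5 at 716 and 694 CPM in the controls and 795 and 765 CPM in the others. The endothelial list did not pass (14 of 20 positive, median 0.15, camera adjusted p = 0.258), nor did the head mesenchyme list (18 of 25 positive, median 0.37, camera adjusted p = 0.281). In the mesenchyme list Col1a1 stood at 1107 and 1207 against 568 and 580 CPM, while Col3a1 stood at 1188 and 1299 against 1300 and 1358 CPM.

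The myogenic list rose, with 8 of 11 measured members positive and a median of 2.81 (camera adjusted p = 5.43e-07; adjusted p = 0.18 with an estimated correlation). When adjusted over the list alone, 5 were higher and 1 was lower. The members with the smallest p were not regulators of muscle fate but parts of the contractile apparatus of striated muscle, the embryonic heart included. Actc1, the cardiac actin, stood at 17.3 and 34.2 CPM in the controls and 145 and 133 CPM in the libraries labelled Brg1cKO, and Tnni1, a troponin, at 0.909 and 0 against 73.8 and 78.6 CPM. Myod1, a regulator of skeletal muscle fate named after its values were seen, stood at 1.23 and 26.9 against 0 and 0.154 CPM.

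**Figure D2:**
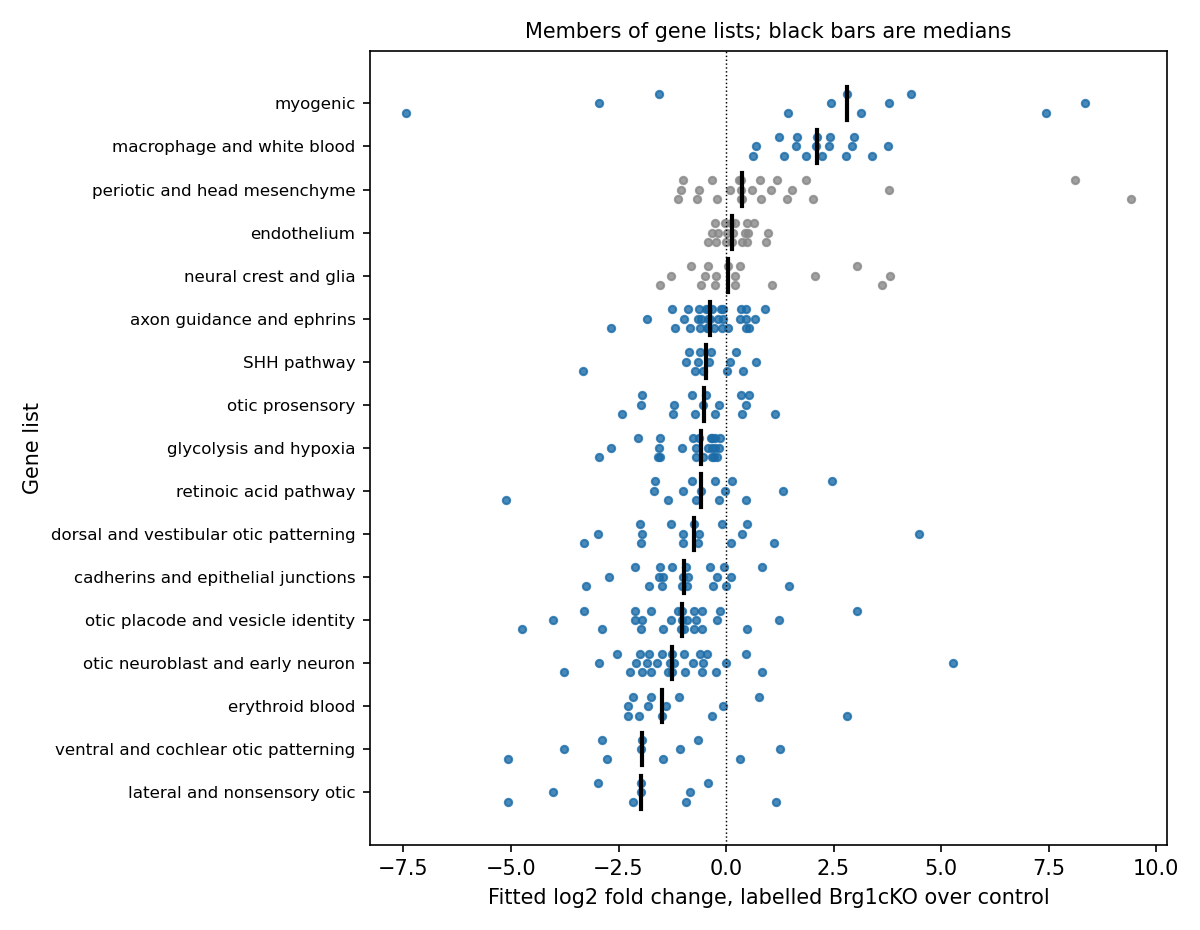
Fitted log2 fold change (labelled Brg1cKO over control) of each measured member of 17 gene lists, with a bar at each median; blue lists passed camera with the preset correlation and grey lists did not. The white blood cell median is 2.11 and the median of the otic placode and vesicle list is -1.02.

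Genes of glycolysis and the hypoxia response fell as a set, with 24 of 24 members negative and a median of -0.58 (camera adjusted p = 1.26e-11; adjusted p = 0.18 with an estimated correlation). Vegfa, a growth factor for blood vessels, stood at 231 and 260 CPM in the controls and 86.1 and 81.3 CPM in the libraries labelled Brg1cKO, and Pfkp, a glycolytic enzyme, at 152 and 105 against 51.0 and 38.0 CPM. This list and the others of this paragraph moved in libraries where the white blood cell list had a median of 2.11, the myogenic list 2.81 and the otic placode and vesicle list -1.02. Cadherins and epithelial junction genes fell, with 19 of 22 negative and a median of -0.97 (camera adjusted p = 1.22e-07; adjusted p = 0.18 with an estimated correlation), and Cdh4 stood at 67.2 and 32.8 against 4.99 and 5.48 CPM. Axon guidance genes fell (24 of 33 negative, median -0.37, camera adjusted p = 0.000932; adjusted p = 0.334 with an estimated correlation). Retinoic acid genes fell as well (11 of 15 negative, median -0.59, camera adjusted p = 0.00468; adjusted p = 0.297 with an estimated correlation). SHH pathway genes had 9 of 14 negative and a median of -0.47 (camera adjusted p = 0.0251; adjusted p = 0.334 with an estimated correlation). Without control replicate 2, the retinoic acid and SHH calls were lost (adjusted p = 0.117 and 0.121).

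In all, 14 of 43 lists passed, 2 higher and 12 lower. With fry, which asks whether a list's genes moved one way, 7 passed, all among the 14. With an estimated correlation 0 passed, although 8 had an unadjusted p under 0.05. The estimated values were -0.0248 for white blood cell genes and 0.000179 for otic placode and vesicle genes, both under the preset 0.01. A higher correlation used in that test thus does not explain the loss of those calls. Resting on 2 residual degrees of freedom, the estimates do not show that members of these lists varied independently. Among the 14 lists the highest was 0.0513, for glycolysis and hypoxia. For independent simulated genes shifted by 4-fold, the camera adjusted p went from 4e-86 to 0.0408, which still passed. The estimated form was thus far less sensitive, but this simulation cannot say why the measured lists did not pass. A list that did not pass is not shown to be unchanged. Lists that did not pass with the preset correlation include SWI/SNF subunits, Smarca4 included (21 of 30 negative, median -0.10, adjusted p = 0.148), FGF (median -0.34, adjusted p = 0.0657), S phase (median 0.21, adjusted p = 0.0807), HOX (median 1.43, adjusted p = 0.118), p53 targets (median 0.23, adjusted p = 0.546) and Notch (median -0.11, adjusted p = 0.207). Without Brg1cKO replicate 1, FGF (adjusted p = 0.00996), HOX (0.0230) and mitochondrially encoded genes (0.0458) did pass, and without control replicate 1 other chromatin remodelers did (0.0422). In 8 lists, none of them past the threshold, the median, the mean and the test differed in sign. These were hair cell, other chromatin remodelers, WNT, cell cycle inhibitors, epibranchial, surface ectoderm, pharyngeal endoderm and replication histones. The medians of the 14 lists kept their sign under the other scalings, and the median over all genes was 0.03 with TMM, -0.01 with RLE and 0.07 with upper quartile scaling.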

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

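The test of captured molecules and the thinning of libraries to the same depth were chosen after the results were seen. Records outside the gene counts differed between the groups. The share that did not align uniquely averaged 8.98% in the libraries labelled Brg1cKO and 7.70% in the controls, and the ambiguous share averaged 2.98% against 2.22%. In both cases the lower library labelled Brg1cKO (8.95% and 2.95%) lay above the higher control (7.76% and 2.23%). No biological explanation was tested for these shares.

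More genes were detected in the libraries labelled Brg1cKO. Thinned to the same 15357265 gene reads, the controls held 17266 and 16925 genes and the others 20180 and 20347, which is 18.5% more and argues against depth as the whole cause. Fewer distinct RNA molecules captured in the controls may also give this pattern. At equal depth the SD of the log2 ratio between replicates was 1.76 times as large in the controls, while genes at 0 in a replicate and at 10 or more reads in the other were 1.46 times as frequent, under the 1.5 times set for the test, so this stays open. A wider mix of cells, or a change of expression that goes with the label, stays open as well.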

How the results depend on the processing

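The newer edgeR moderation, the thinned libraries and voom with quality weights were chosen after seeing the data. The 5 calls were all kept under 18 of 20 alternatives, the exceptions being Tmsb4x without robust moderation (4 genes called, adjusted p = 0.0656 for Tmsb4x, range over its alternatives 6.38e-56 to 0.0656) and with a minimum of 2-fold (4 called). The count of changed genes was 417 (164 higher, 253 lower) with every gene of at least 1 count, 10 (4 and 6) with a minimum count of 50, 2422 (1379 and 1043) with DESeq2, 54 (20 and 34) with voom, 38 (15 and 23) at an adjusted p under 0.10, 70 (34 and 36) with the newer moderation and 152 (30 and 122) with quality weights. Without robust moderation and with the 2-fold minimum, 1 gene was higher and 3 were lower. Leaving out a library gave 33 to 3519 changed, 19 to 1760 higher and 14 to 1759 lower, and the lone library left in a group is then assumed to vary like the other group. RLE and total count scaling, a filter at 1 CPM in 2 libraries, and thinning gave 6 calls (2 higher, 4 lower), with Col1a1 added. The cause of these differences was not tested, but DESeq2 made 81 and 101 calls on simulated counts with no change, and edgeR 0 in both. Those counts were drawn with dispersions estimated by edgeR, which may favour it. No shared deviation of same-numbered libraries was seen (correlation -0.00528 over all tested genes, -0.00398 at a log2 CPM of at least 5). That does not show that they were unpaired, which the labels do not say. With the replicate block 140 genes were called, 71 higher and 69 lower.

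The number of lists past the threshold was 12 to 17, except 0 with an estimated correlation and 7 with fry. Without mitochondrial, ribosomal protein and haemoglobin genes the erythroid call was lost (adjusted p = 0.459), since its globins are taken out and 7 members are left. Of 814 list values, 773 stayed on their side, 26 were lost, 15 were gained and 0 reversed. FGF passed with every gene of at least 1 count (0.00928), with the replicate block (0.0456) and without Brg1cKO replicate 1 (0.00996), and SWI/SNF subunits with every gene of at least 1 count (0.0434). S phase passed with a minimum count of 50 (0.0349), voom (0.0274) and quality weights (0.0240), and HOX without Brg1cKO replicate 1 (0.0230) and with thinning (0.0155). Mitochondrially encoded and ribosomal protein genes passed with voom (0.000217 and 0.0136) and quality weights (9.77e-05 and 0.00859), the former also without Brg1cKO replicate 1 (0.0458), and other chromatin remodelers without control replicate 1 (0.0422). Of 3489 values of named genes, 2922 stayed on their side of the threshold in the same direction, 565 passed where the main test had not, 1 was lost and 1 reversed. The reversed value was that of Foxa1, -0.02 in the main test, at 2.05 (adjusted p = 0.0305) without control replicate 1 and -0.86 without control replicate 2. Its adjusted p ran from 0.0305 to 1 over its alternatives, and the cause was not tested. A further 27 values changed sign with no call on either side. Smarca4 ranged from 0.06 to 0.14 and Sox2 from 0.94 to 1.37, with an adjusted p of at least 0.518 and 0.0521. At these depths edgeR recovered a 4-fold change in 26% to 40% of simulated genes above a minimum average CPM. Recovery at lower counts was not measured. A gene that did not pass is thus not shown to be unchanged.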

Other observations

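The test of a lower share of otic cells and the thinning to equal depth were chosen after the results were seen. The added lists of macrophage, heart muscle and skeletal muscle genes were chosen after the fixed lists had been tested, without their own values having been looked at. Genes of heart muscle had positive fold changes in the libraries labelled Brg1cKO, with no gene past the threshold and no set test run. Of 28 listed genes 23 were measured, and 23 of 23 had positive log2 fold changes, with a median of 4.21 (4.15 with Pln, at 0 in both controls, set to its bound). The lowest adjusted p over all genes tested was 0.110, for Myh6 and Tbx20 (edgeR). The controls lay far apart for many of them. Myh7, a heart myosin, stood at 108 and 44.9 against 263 and 260.5 CPM and Myh6 at 18.0 and 7.64 against 113 and 119 CPM. The regulators Tbx20, Gata4 and Hand2 stood at 0.260 and 2.92 against 117 and 111, 0.390 and 5.46 against 70.9 and 91.7, and 7.28 and 0 against 79.2 and 54.7 CPM. Tnnt2 averaged 19.6 ± 12.1 against 58.1 ± 7.74 CPM (SD, n = 2 each) and Myl7 stood at 3.05 and 0 against 42.4 and 38.8 CPM. None of the 28 stands in a list fixed earlier. Genes rare in the controls could be measured only where they were higher in the other group, but of the 8 at 1 CPM or more in both controls, a set looked at after the values were seen, 8 were positive as well, with a median of 2.34. Genes that did not pass the filter on counts, which asks for enough reads in more than a single library, were Nppa (1 read over the 4 libraries), Sln (0), and Nppb, Mybphl and Bmp10, with 0 reads in both controls and 108 and 0, 62 and 0, and 7 and 12 reads in Brg1cKO replicates 1 and 2.

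Genes at 0 in both controls and at 10 CPM or more in both libraries labelled Brg1cKO numbered 13, all named after their values were seen, with a lowest adjusted p of 0.0840, for Csf2rb (edgeR). Against 3 counts over the group, Ccl2, a chemokine, was at least 344-fold higher and Csf2rb, a cytokine receptor chain, at least 335-fold. For Gata5, a transcription factor of heart and endoderm, and Myl3, a heart myosin light chain, the bounds were 273-fold and 268-fold. In the opposite direction 4 genes without a functional name were at 0 in both libraries labelled Brg1cKO. The bounds cover counting error only. At equal depth, 2987 genes were at 0 in a control replicate and at 10 or more reads in the other. Between the libraries labelled Brg1cKO, 2047 were. A 0 in a control can thus be a failure of capture, and the imbalance of 13 against 4 genes was not tested against that. The hindbrain list did not pass (12 of 23 positive, camera adjusted p = 0.21), with 8 members at 0 in a group. In it, Pax3 stood at 0 and 0 CPM in the controls and 5.19 and 8.95 CPM in the others, and Nkx6-2 at 0 and 0 against 4.06 and 15.1 CPM. The immediate early and heat shock list did not pass either (14 of 24 positive, camera adjusted p = 0.179). In it, Zfp36 stood at 75.0 and 82.6 against 254 and 204 CPM, while Hspa1b, a heat shock gene, stood at 38.3 and 38.2 against 5.46 and 4.09 CPM. Xist was found in every library together with Kdm5d, a Y-linked gene. Xist stood at 260 and 281 against 412 and 432 CPM and Kdm5d at 57.4 and 52.2 against 17.2 and 29.5 CPM. Uty, Eif2s3y and Ddx3y, also Y-linked, had log2 fold changes of -1.76, -1.14 and -0.64, and none of these genes passed. The sex-linked list did not pass (camera adjusted p = 0.172). A different mix of male and female embryos was not tested and cannot be told apart from the label.

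Genes of white blood cells and the myogenic list were higher in the libraries labelled Brg1cKO, while endothelial and mesenchymal lists did not pass and the erythroid list was lower. At equal depth the medians of the white blood cell and myogenic lists were 2.11 and 2.98. Fold changes were already scaled for library size, so thinning could hardly have removed medians of this size and decides little. It also leaves unequal capture of molecules untouched. After a trend on gene length and GC content was taken out, the white blood cell median was 2.13, which argues against length or GC bias for that list. More white blood cells among the sorted cells is a candidate explanation. Of a further macrophage list, 92.9% were positive (26 of 28, median 1.60), and 16 of its 30 genes were at 1 CPM or more in both controls. No member passed (lowest adjusted p = 0.121, for Lcp1 and Rac2, edgeR), and no set test was run. Lcp1 averaged 161 against 339 CPM and Stab1 431 against 734 CPM, both outside the rule for named genes. Stab1 stood above Csf1r (81.6 CPM) in the controls, so cells other than white blood cells may also give it. Heart cells or their RNA are another candidate explanation. Of the measured heart genes 100% were positive, but those rare in the controls could be measured only where they were higher in the other group. Of the 8 at 1 CPM or more in both controls, looked at after the values were seen, 8 were positive, with a median of 2.34. Heart precursors and expression of these genes within otic cells, neither of them tested, stay open beside heart muscle cells. For skeletal muscle, 66.7% of 9 genes (median 2.58) were positive, which decides nothing. The sort was meant to keep otic cells, and whether it or the label sets the difference cannot be read from 4 libraries.

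Otic genes were lower in the libraries labelled Brg1cKO. The median of the otic placode and vesicle list was -1.04 at equal depth. Thinning could hardly have removed a scaled median of this size, so it decides little about depth. After the trend on length and GC content was taken out the median was -1.03, which argues against length or GC bias as the whole cause. A lower share of otic cells as the only difference in make-up would raise other cell types alike, but the white blood cell median (2.11, quartiles 1.64 and 2.80) lay 3.60 above the erythroid median (-1.49, quartiles -2.02 and -0.32). The erythroid call was lost without globins and mitochondrial and ribosomal protein genes (adjusted p = 0.459), where the 7 erythroid genes left had a median of -0.32 (quartiles -2.22 and 0.34) and Slc4a1 stood at -2.28, but the endothelial list, with a median of 0.15 and quartiles of -0.06 and 0.48, also lay below the white blood cell quartiles. A lower share of otic cells together with other changes in the sorted mix, and lower expression within otic cells that goes with the label, may each give this pattern and stay open.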
